A study of Mus musculus with 20 samples.

How the data were processed

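RNA of the ascending and the descending thoracic aorta of C57BL/6J mice given water or BAPN for 1 week was sequenced in 20 libraries, 5 for each of the 4 combinations of region and treatment. Per the labels' protocols, RNA was taken with a column kit for fibrous tissue and made into libraries from 1 µg of total RNA. The deposited values are raw counts of reads per gene for 54532 Ensembl genes, in 1 table for the series and 1 file per library; the 20 per-library files were checked and equal the table. Per the submitters' processing notes, fastp, STAR 2.5 and HTSeq 0.6.1 were used with the mm10 genome. Neither their settings nor the gene annotation is stated, so symbols, chromosomes and coordinates are those of GENCODE mouse annotation on GRCm38 (54409 gene IDs matched, 123 did not). Of the genes, 30946 had at least 1 count. Totals ran from 15.7 M to 23.3 M counts per library. Their means were 19.7 M (SD 2.13 M) in ascending water, 17.3 M (SD 1.33 M) in ascending BAPN, 18.2 M (SD 1.46 M) in descending water and 18.6 M (SD 1.67 M) in descending BAPN. Eln took 3.35% of all counts, Sparc 1.36%, Acta2 1.31% and mt-Co1 1.18%.

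Groups were read from the labels. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 15543, and libraries were scaled by the trimmed mean of M values. One quasi-likelihood model in edgeR 4.0.16 (R 4.3.3) with a coefficient for each group gave 16 residual degrees of freedom. From it came 5 comparisons: BAPN against water in each region, descending against ascending aorta under each treatment, and the difference of the BAPN effect between the regions. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes under 0.05 are called. Standard errors are those of the log2 difference. Levels are CPM with the SD over 5 libraries. The median SE of the difference of effects was 0.124 on the log2 scale. Where a group held 0 counts of a gene, a bound was computed against 3 counts over the group, and with 1 to 3 counts the ratio of counts is given with its 95% interval; bounds and intervals cover counting error only.

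Before the data were examined, 43 gene lists, the comparisons, the alternatives named below except those on batch, and the rule for naming genes were fixed. The rule names, in each region's response to BAPN, in the regional comparison under water and in the difference of effects, the 8 called genes with the largest and the 8 with the most negative log2 difference among those with a mean of at least 5 CPM, leaving out predicted genes, pseudogenes and immunoglobulin or T cell receptor segments. It adds up to 4 members with the smallest p of each list described, and always Lox, Loxl1 to Loxl4 and Eln. Where no gene was called, the 5 with the smallest p are named as such. Lists with at least 3 tested members were tested with camera in limma 3.58.1 (preset correlation 0.01), adjusted over the lists of 1 comparison. As alternatives camera was run with a correlation estimated from the residuals, and fry was run. Fisher's exact test of the overlap of calls assumes independent regions, which the labels do not settle, so only counts are given. A set of clock genes was written after the ranking was seen, and no test of its response to BAPN is given. Of 2 lists of genes held out from it, also written then, camera p-values are not adjusted.

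Alternatives for the other choices were relative log expression factors, upper-quartile scaling, no filter on low counts, a stricter filter (at least 1 CPM in 5 libraries), DESeq2 1.42.0, limma-voom, a fit to the 2 compared groups alone, the replicate number as a block, a size threshold of 1 on the log2 scale, leaving out genes of other tissues, and leaving out each library in turn. After the data were seen, batches were read from the first principal component of 33 pseudogenes with a mean of at least 2 CPM. They were picked by the mark -ps in their symbol, and whether each is a processed copy was not checked. A batch term, and fits within each batch, were added. Simulated counts of all 20 libraries were drawn from a negative binomial distribution, with 1 mean per gene and the fitted dispersions. Known genes with a mean of at least 5 CPM were changed in 1 group, with no batch or pairing. The pipeline was tested on these data. In the ascending comparison it recovered 61.2% of genes changed 1.25-fold, 97.0% of those changed 1.5-fold and 100% of those changed 2-fold, with 8 false calls among 180; for the difference of effects it recovered 25.4%, 77.6% and 98.5%, with 4 false among 138. Figures were drawn with matplotlib 3.10.9. Isoforms, splicing and sequence variants were not analysed here, and single members of some gene lists, although counted, are not reported here by name.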

Results

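The libraries hold RNA of the ascending or the descending thoracic aorta of C57BL/6J mice given water or β-aminopropionitrile (BAPN) for 1 week, with 5 libraries in each of 4 groups. BAPN blocks the lysyl oxidases, the enzymes that cross-link elastin and collagen. Levels are CPM (mean and SD, n = 5 libraries per group). Differences are log2 ratios from edgeR with their standard error (SE), and a gene is called when its p-value, adjusted over the 15543 genes tested, is under 0.05. In a principal component analysis the first component (64.2% of the variance) parted the regions and the second (4.87%) parted treated from water libraries. The levels of 33 pseudogenes, picked by the mark -ps in their symbol, parted the libraries in another way. There was a set with higher levels (ascending water 4 and 5, ascending BAPN 1 to 5, descending water 1, 2 and 5) and a set with lower levels (the others). Of the 33, 22 had a positive difference between the sets in the model with batch as a term, so not all carry the split. The gap between these sets on the pseudogenes' first component was 1.56, against at most 0.407 between neighbours within a set. The sets are treated below as 2 batches, a division chosen after seeing the data, and values within a batch are given beside some of those from all libraries. The labels do not say whether libraries come from separate animals, so the p-values measure the spread between these samples only.

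In the ascending aorta, BAPN was followed by more transcript of its own target and less transcript of the proteins that the target cross-links. Lox, the main vascular lysyl oxidase (ENSMUSG00000024529, GRCm38 chromosome 18, 52516067 to 52529867), rose from 733 (SD 48.3) to 870 (SD 39.0) CPM, a log2 difference of 0.25 (SE 0.05, adjusted p = 0.00329) with no overlap between the groups' libraries. Eln, which encodes elastin (ENSMUSG00000029675, chromosome 5, 134702593 to 134747323), decreased from 26580 (SD 1537) to 20010 (SD 902), a 1.33-fold lower level (log2 -0.41, SE 0.07, adjusted p = 0.000303). Col3a1, the fibrillar collagen that runs beside elastic lamellae, went from 10650 (SD 359) to 8811 (SD 357), log2 -0.27 (SE 0.04, adjusted p = 0.000236). Sparc, a secreted collagen-binding chaperone, went from 11840 to 9497 CPM, log2 -0.32 (SE 0.04). Within the batch that holds 2 ascending water and all 5 ascending BAPN libraries, the log2 differences were 0.30 (SE 0.05, adjusted p = 0.005) for Lox and -0.32 (SE 0.04, adjusted p = 0.00076) for Eln.

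By fixed gene lists, fibrillar collagens had 0 members higher and 6 lower of 10 tested (camera adjusted p = 1.08e-08, 0.0605 with an estimated correlation), with a median log2 difference of -0.235. Chondrocyte genes, a list that shares Col2a1 and Col11a2 with this one, also lay lower (median -0.173, adjusted p = 0.0068, 0.396 with an estimated correlation). With batch as a term the call was lost although the median was -0.256 (adjusted p = 0.063). Within the batch it was kept (median -0.31, adjusted p = 0.023). The elastic fibre list had 0 higher and 5 lower of 18 (adjusted p = 1.41e-05, 0.076 with an estimated correlation). These were Eln, Mfap5, Mfap4, a microfibril protein, at -0.39 (SE 0.05), Fbln5, which tethers elastin to the cell, at -0.19 (SE 0.04), and, named after its values were seen, Ltbp3. Collagen processing had 0 higher and 9 lower of 20 (adjusted p = 1.83e-05, 0.212 with an estimated correlation), including the procollagen protease Bmp1 (-0.26) and the prolyl hydroxylase P3h3 (-0.25). Adjusted over the list alone, the counts of these 3 matrix lists were 0 and 9, 0 and 5, and 1 and 10. They kept their calls within the batch (adjusted p = 3e-06, 0.00014 and 0.0013), while Fbln5 (-0.15, SE 0.05, adjusted p = 0.11) and Mfap5 (-0.14, SE 0.04, adjusted p = 0.094) did not. The lysyl oxidase family as a list was not called (1 higher and 1 lower of 5, adjusted over the list alone 1 and 2; adjusted p = 0.566). Loxl1, which acts on tropoelastin, was lower at -0.15 (SE 0.05, adjusted p = 0.045), but not within the batch (-0.07, SE 0.05, adjusted p = 0.55). That call was also lost on leaving out any of 11 single libraries (ascending water 1, 2, 3 or 4, ascending BAPN 1, 2, 4 or 5, descending BAPN 1, 3 or 4; adjusted p = 0.052 to 0.12). Loxl2 (-0.06, SE 0.06), Loxl3 (-0.04, SE 0.05) and Loxl4 (-0.27, SE 0.10) did not pass.

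Among genes that break down or remodel matrix, Mmp3 (stromelysin) rose from 13.2 (SD 1.26) to 25.5 (SD 1.89) CPM, log2 0.95 (SE 0.11, adjusted p = 5.38e-06), and Mmp14, a membrane-bound collagenase, rose at 0.32 (SE 0.06). The protease and inhibitor list had 6 higher and 2 lower of 25 and was not called (adjusted p = 0.384). Its median (-0.0356) and its mean (0.0569) differ in sign, and the test points up. Its 2 lower members, named after their values were seen, were the osteoclast protease gene Ctsk (-0.32) and Mmp23 (-0.19). Of the basement membrane genes 0 were higher and 3 lower of 18 (adjusted p = 0.298), which were the type IV collagen chains Col4a4 (-0.37, SE 0.05) and Col4a3 (-0.35, SE 0.05) and the agrin gene Agrn (-0.16, SE 0.04; not called within the batch, adjusted p = 0.057). Of the matricellular genes 1 was higher and 2 lower of 17 (adjusted p = 0.521): Ccn3, which restrains smooth muscle growth, at 0.43 (SE 0.05) and Ccn5 at -0.54 (SE 0.10), with the tenascin gene Tnxb at -0.20 (SE 0.06). The call of Tnxb was lost on leaving out any of 9 single libraries (ascending water 1, 3 or 5, ascending BAPN 1, 2 or 4, descending water 3, descending BAPN 2 or 3; adjusted p = 0.05 to 0.13).

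Contractile genes moved the other way from the matrix genes. Acta2, smooth muscle actin (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590), rose from 11450 (SD 464) to 14270 (SD 689) CPM (log2 0.32, SE 0.05, adjusted p = 5.39e-05). Myocd, the coactivator that turns on the contractile programme, rose from 93.8 (SD 8.77) to 137 (SD 6.19), log2 0.54 (SE 0.08). The contractile list had 7 higher and 0 lower of 23 (adjusted p = 5.55e-08, 0.212 with an estimated correlation; adjusted over the list alone 14 and 1). The integrin and focal adhesion list had 10 higher and 0 lower of 26 (adjusted p = 6.62e-06, 0.33 with an estimated correlation; list alone 12 and 0). Among its members were the adhesion proteins Tes (0.48, SE 0.06), talin Tln1 (0.28, SE 0.05) and vinculin Vcl (0.28, SE 0.06). Within the batch both lists passed (adjusted p = 1.2e-12 and 5.6e-08). Beside these, the cardiomyocyte list had 3 higher and 0 lower of 19 (adjusted p = 1.83e-05, 0.454 with an estimated correlation; list alone 10 and 0), and its median log2 difference, 0.485, exceeded that of the contractile list, 0.118. Its 3 called members each lost the call when a single library was left out: Actn2 (0.59, SE 0.15) without ascending water 3 or ascending BAPN 4 (adjusted p = 0.052 and 0.062), and Myl3 (0.91, SE 0.23) without ascending water 3 or ascending BAPN 1 (0.052 and 0.059). Tnnt2 (0.43, SE 0.12) lost it without ascending water 2, 3 or 4 or ascending BAPN 3, 4 or 5 (0.054 to 0.14). None of these 3 passed within the batch (adjusted p = 0.26, 0.43 and 0.13), where the list itself passed (0.0013) with a smaller median, 0.272, against 0.188 for the contractile list. With batch as a term its median was 0.27 (0.0072).

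Hspa5, the chief chaperone of the endoplasmic reticulum (ENSMUSG00000026864, chromosome 2, 34771970 to 34777547), rose from 458 (SD 15.9) to 575 (SD 28.1), log2 0.33 (SE 0.04, adjusted p = 8.39e-06), with its co-factors Hyou1 (0.28, SE 0.05) and Dnajc3 (0.20, SE 0.04). The unfolded protein response list had 7 higher and 1 lower of 25 (adjusted p = 3.82e-05, 0.0605 with an estimated correlation; list alone 11 and 2; within the batch 0.003). The lower member, named after its values were seen, was Herpud1 (-0.18, SE 0.05), which feeds unfolded proteins to degradation. Cell cycle genes were lower: Mki67, the proliferation antigen, fell from 15.1 (SD 0.82) to 10.02 (SD 1.92) CPM (log2 -0.59, SE 0.12, adjusted p = 0.00199). Cdk1, the mitotic kinase, fell from 4.81 (SD 0.79) to 2.59 (SD 0.66), log2 -0.89 (SE 0.18). The cell cycle list had 1 higher and 14 lower of 27 (adjusted p = 8.28e-18, 0.0605 with an estimated correlation; list alone 1 and 24; median -0.583, within the batch -0.596 with adjusted p = 1.2e-12). Within the batch Cdk1 passed (-1.05, adjusted p = 0.021) and Mki67 did not (-0.58, adjusted p = 0.057). The 1 higher member, named after its values were seen, was the replication licensing factor Mcm6 (0.17, SE 0.05).

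The genes with the largest changes in the ascending aorta included several of the circadian clock. Arntl, which encodes BMAL1, the positive arm of the clock (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126), rose 4.55-fold, from 7.82 (SD 2.42) to 36.0 (SD 5.44) CPM (log2 2.19, SE 0.16, adjusted p = 2.02e-09). Dbp, a transcription factor that BMAL1 drives (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203), was 5.24-fold lower, from 171 (SD 22.0) to 32.7 (SD 7.45), log2 -2.39 (SE 0.15, adjusted p = 1.46e-10). Among the 8 genes that rose most were also the BMAL1 partner Npas2 (1.44, SE 0.15) and the repressors Nfil3 (1.46, SE 0.28) and Cry1 (0.98, SE 0.15). The others were the zinc finger gene Zbtb16 (1.38, SE 0.14), the co-chaperone Fkbp5 (0.98, SE 0.10), the pericyte factor Foxs1 (1.26, SE 0.19) and the small GTPase gene Rasl10b (1.16, SE 0.15). Among the 8 that fell most were Per3 (-1.81, SE 0.12), Tef (-1.18, SE 0.08), Hlf (-1.12, SE 0.09) and Bhlhe41 (-1.24, SE 0.10), all of the clock's negative arm or output. With them were the titin cap gene Tcap (-1.63, SE 0.17), the phosphatase inhibitor Ppp1r1b (-1.06, SE 0.18) and the imprinted gene Nnat (-1.15, SE 0.30). The Nnat call was lost without ascending water 5 (adjusted p = 0.068) or ascending BAPN 2, 3 or 4 (0.051, 0.054 and 0.058). A set of 15 clock genes was chosen after the values were seen and by the direction seen, so its number of calls is no test. The clock genes Per1, Nr1d1 and Usp2, left out of it, had a median of -0.461, and of them only Nr1d1 was called lower. Within the batch Nr1d1 was not called (adjusted p = 0.359) and Per1 was (-0.75, adjusted p = 0.0125). Within the batch Arntl was at 2.15 and Dbp at -2.29.

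In all, 986 genes were called in the ascending aorta, 534 higher and 452 lower under BAPN, of which 43 changed at least 2-fold (12 higher, 31 lower). The balance of directions depends on the setting, at 449 higher and 529 lower under upper-quartile scaling and 434 and 517 without a filter on low counts. With batch as a term the count was 542 (330 higher, 212 lower), and within the batch of 2 water and 5 BAPN libraries it was 483 (270 higher, 213 lower). Of the 43 lists 12 were called, 6 in each direction, and 0 with an estimated correlation; 20 were called without ascending water 1. The self-contained test fry called 9. Fry asks whether a list's genes move on balance one way and, in its mixed form, whether they change in either direction, and neither form compares the list with other genes. Interferon response genes had 0 higher and 2 lower of 23 (adjusted p = 0.00592, 0.795 with an estimated correlation; list alone 0 and 2), named as the antiviral genes Ifit3b (-1.13, SE 0.19) and Ifit3 (-0.62, SE 0.16). The list call was lost without ascending BAPN 4 (adjusted p = 0.099), and that of Ifit3 without ascending water 4 or ascending BAPN 4 (0.053 and 0.062). Macrophage genes had 1 higher and 0 lower of 25 (adjusted p = 0.496), the resident macrophage receptor Lyve1, named after its values were seen.

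**Figure D1:**
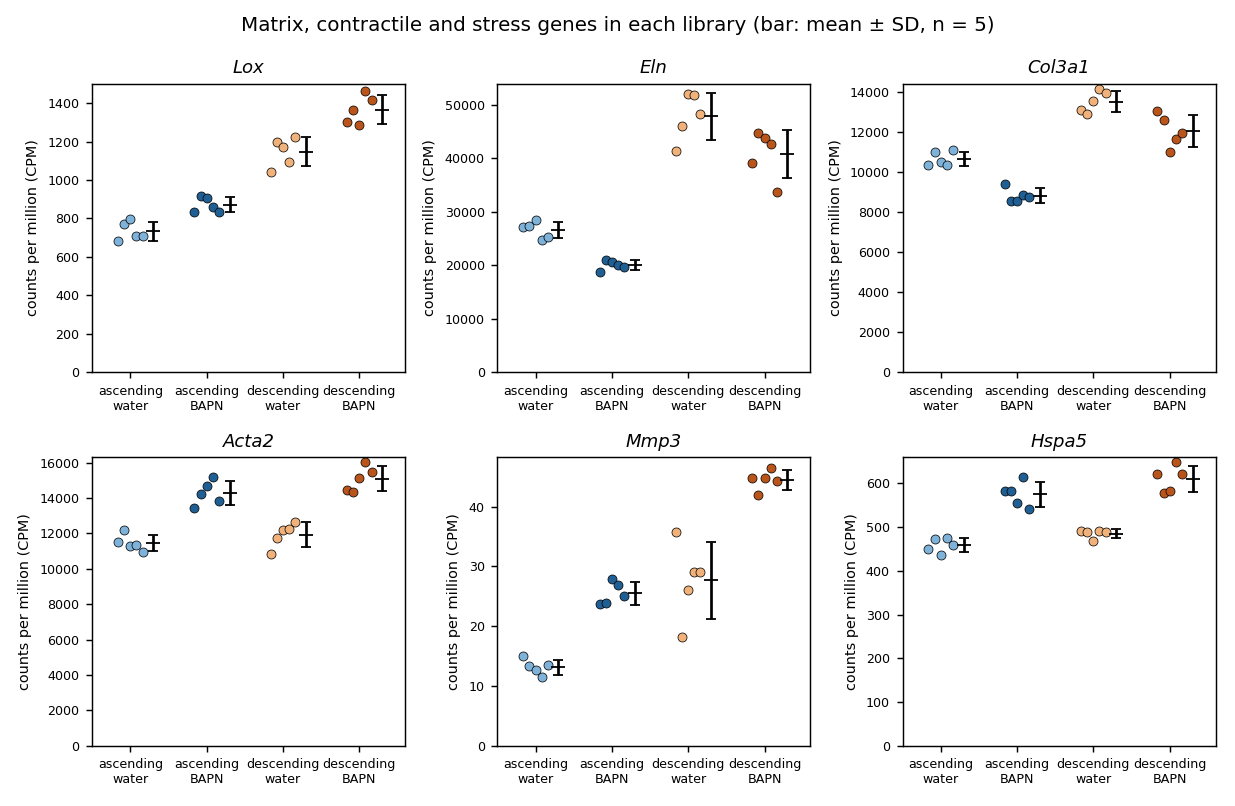
CPM of Lox, Eln, Col3a1, Acta2, Mmp3 and Hspa5 in each library, with mean and SD (n = 5 per group).

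**Figure D2:**
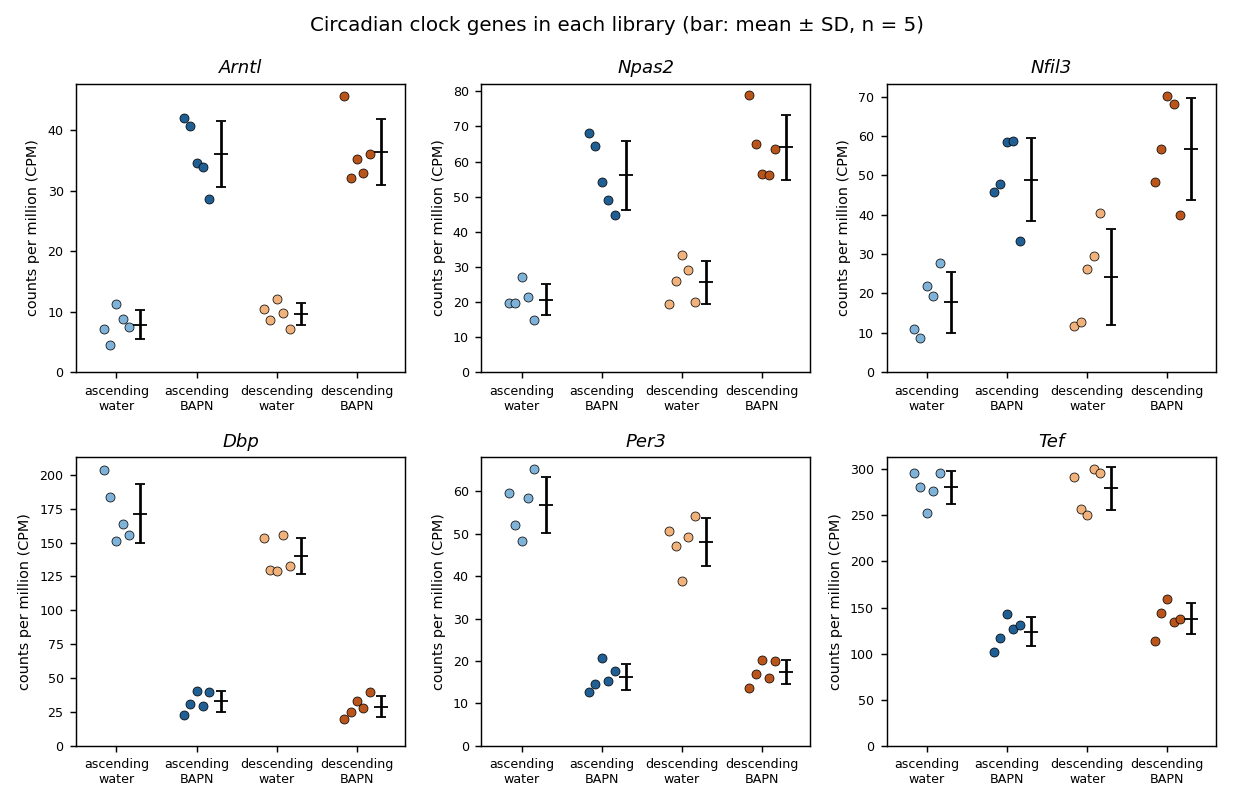
CPM of Arntl, Npas2, Nfil3, Dbp, Per3 and Tef in each library, with mean and SD (n = 5 per group).

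In the descending aorta BAPN was again followed by more Lox transcript and less of several elastic fibre transcripts. Lox rose from 1147 (SD 75.8) to 1366 (SD 74.8) CPM, log2 0.25 (SE 0.05, adjusted p = 0.00178). Within the batch of 2 water and 5 BAPN libraries it rose by 0.26 (SE 0.06, adjusted p = 0.042). Fbln5 fell from 1220 (SD 25.6) to 1001 (SD 46.1), log2 -0.29 (SE 0.04, adjusted p = 1.25e-05). Mfap4 fell from 1606 (SD 121) to 1294 (SD 31.2), log2 -0.31 (SE 0.05, adjusted p = 7.67e-05). Eln went from 47870 (SD 4403) to 40750 (SD 4517), log2 -0.23 (SE 0.07, adjusted p = 0.0247), and was at -0.35 within the batch (SE 0.09, adjusted p = 0.058). The Eln call was lost without descending water 3 or 4 (adjusted p = 0.079 and 0.066) or descending BAPN 1 or 5 (0.061 and 0.068). Col3a1 was lower at -0.16 (SE 0.04, adjusted p = 0.0151), but not called without descending BAPN 3 (0.054) or within the batch (-0.20, SE 0.07, adjusted p = 0.15).

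As lists, the elastic fibre genes (0 higher and 4 lower of 18, adjusted p = 0.138; adjusted over the list alone 2 and 4) and the fibrillar collagens (0 and 2 of 10, adjusted p = 0.145; list alone 0 and 2) were not called in the descending aorta. Collagen processing had 0 higher and 4 lower of 20 (adjusted p = 0.0483, 0.835 with an estimated correlation; list alone 0 and 5), including Sparc (-0.17, SE 0.04) and P3h3 (-0.18, SE 0.04; within the batch -0.30). That list call was lost on leaving out any of 10 single libraries (ascending water 3 or 5, ascending BAPN 2 or 4, descending water 3, 4 or 5, descending BAPN 3, 4 or 5; adjusted p = 0.052 to 0.15), and within the batch it passed (0.0015). The lysyl oxidase family had 1 higher and 1 lower of 5 (adjusted p = 0.884). The lower member was Loxl4, at -0.33 (SE 0.10, adjusted p = 0.0383). It lost its call without descending water 2 or 4 (0.13 and 0.06) or descending BAPN 3, 4 or 5 (0.061, 0.11 and 0.1), and within the batch (-0.28, SE 0.13, adjusted p = 0.31). Loxl1 (-0.01, SE 0.05), Loxl2 (-0.10, SE 0.06) and Loxl3 (-0.04, SE 0.05) did not pass. Basement membrane genes had 7 higher and 0 lower of 18 (adjusted p = 0.00321, 0.779 with an estimated correlation; list alone 10 and 0), with the laminin chain Lama5 at 0.22 (SE 0.05). Neither the list (adjusted p = 0.26) nor Lama5 (0.10, SE 0.06, adjusted p = 0.46) passed within the batch.

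The protease genes Mmp14 (0.45, SE 0.06, from 180 to 246 CPM, adjusted p = 8.15e-06), Mmp3 (0.68, SE 0.10, from 27.7 to 44.4) and Plat, the tissue plasminogen activator (0.35, SE 0.05), rose in the descending aorta. Their list had 6 higher and 1 lower of 25 (Mmp23, named after its values were seen) and was not called (adjusted p = 0.0545). Ccn3 rose from 584 (SD 26.96) to 903 (SD 52.9), log2 0.63 (SE 0.05, adjusted p = 5.72e-09). The matricellular list had 4 higher (also Tnc, Fn1 and Thbs1) and 3 lower of 17 (Cthrc1, Ccn5 and Comp; adjusted p = 0.375). Of these Thbs1, Ccn5 and Comp were named after their values were seen. The integrin and focal adhesion list had 13 higher and 0 lower of 26 (adjusted p = 1.16e-08, 0.268 with an estimated correlation; list alone 16 and 1; within the batch 3e-04). In it were the fibronectin receptor chain Itga5 at 0.63 (SE 0.11) and Tln1 at 0.30 (SE 0.05). YAP/TAZ targets, genes switched on by mechanical load, had 7 higher and 0 lower of 21 (adjusted p = 0.000217, 0.234 with an estimated correlation; list alone 8 and 1; within the batch 0.0016). In it were Crim1, a growth factor binding protein, at 0.41 (SE 0.05) and the kinase gene Lats2 at 0.38 (SE 0.06). Acta2 rose from 11930 (SD 693) to 15080 (SD 715), log2 0.34 (SE 0.05, adjusted p = 1.77e-05), and Myocd by 0.56 (SE 0.08). The contractile list had 6 higher and 0 lower of 23 (adjusted p = 0.00063, 0.779 with an estimated correlation; list alone 7 and 0), passed within the batch (0.04) and did not with batch as a term (0.095). Beside it, the cardiomyocyte list had 0 higher and 0 lower of 19 (adjusted p = 0.898).

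Cell cycle genes were lower in the descending aorta, with the smallest adjusted p of its 43 lists. Top2a, the mitotic topoisomerase, fell from 18.8 (SD 1.03) to 9.44 (SD 2.02) CPM (log2 -0.99, SE 0.14, adjusted p = 3.19e-05), and Mki67 from 20.6 (SD 2.32) to 11.3 (SD 1.70), log2 -0.86 (SE 0.11). Cdc20, the activator of the anaphase complex (ENSMUSG00000006398, chromosome 4, 118432901 to 118437352), fell from 8.58 (SD 1.12) to 3.79 (SD 0.37), log2 -1.18 (SE 0.13). The list had 0 higher and 23 lower of 27 (adjusted p = 4.72e-34; list alone 0 and 25), with a median of -0.869, or -0.897 within the batch (adjusted p = 5.2e-36). No other list kept its call with an estimated correlation in this comparison (cell cycle adjusted p = 0.00537). Hspa5 rose from 485 (SD 9.79) to 610 (SD 29.6), log2 0.33 (SE 0.04, adjusted p = 4.67e-06), and Xbp1, a transcription factor of the same stress response, by 0.29 (SE 0.04). The unfolded protein response list had 4 higher and 1 lower of 25 (adjusted p = 0.00579, 0.279 with an estimated correlation; list alone 9 and 3; within the batch 0.048), and the lower member was again Herpud1 (-0.27, SE 0.05). The interferon list had 1 higher (Ifit2) and 5 lower of 23 (Ifit3, Ifit3b and Isg15, and, named after their values were seen, Ifi27l2a and Usp18). Its median was -0.32 (adjusted p = 0.00085, 0.835 with an estimated correlation, list alone 1 and 5). With batch as a term the list kept its call (median -0.268, adjusted p = 0.037). Within the batch it was not called, at a median of -0.265 (0.075), nor were Ifit3 (0.26), Ifit3b (0.24) and Isg15 (0.48). Leaving out 1 library ended the calls of Ifit2 (descending water 3, 4 or 5, descending BAPN 4 or 5; 0.05 to 0.1) and Ifit3 (descending water 1 or 2, descending BAPN 1 or 5; 0.05 to 0.061). It also ended those of Ifit3b (descending water 1, 2 or 3, descending BAPN 1, 3 or 4; 0.052 to 0.073) and Isg15 (descending water 1, 2, 3 or 5, descending BAPN 3, 4 or 5; 0.055 to 0.097).

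Clock genes were again among those with the largest changes in the descending aorta. Arntl rose 3.79-fold, from 9.57 (SD 1.86) to 36.4 (SD 5.42) CPM (log2 1.92, SE 0.16, adjusted p = 1.33e-08). Dbp was 4.82-fold lower, from 140 (SD 13.2) to 29.0 (SD 7.74), log2 -2.27 (SE 0.15, adjusted p = 5.43e-10). Per1, Nr1d1 and Usp2 had a median of -0.354, and again only Nr1d1 was called lower (within the batch 0.132). Within the batch Arntl was at 1.74 and Dbp at -2.30. Cry1 (1.40, SE 0.15), Npas2 (1.33, SE 0.15), Nfil3 (1.23, SE 0.28), Zbtb16 (1.46, SE 0.14) and Foxs1 (1.20, SE 0.18) were among the 8 that rose most. So were the lipid kinase gene Dgkg (0.99, SE 0.15, and within the batch 0.58, adjusted p = 0.076) and the non-canonical poly(A) polymerase gene Tent5b (0.95, SE 0.16). Per3 (-1.47, SE 0.12), Hlf (-1.40, SE 0.09), Bhlhe41 (-1.21, SE 0.10), Tcap (-1.80, SE 0.18), Ppp1r1b (-1.31, SE 0.19) and the irisin precursor Fndc5 (-1.31, SE 0.19) were among the 8 that fell most. In all, 1667 genes were called, 961 higher and 706 lower, and 113 of them changed at least 2-fold (18 higher, 95 lower). Upper-quartile scaling turned this balance, to 706 higher and 874 lower. The count was 1126 with batch as a term (629 higher, 497 lower) and 430 within the batch (218 higher, 212 lower). Of the 43 lists 8 were called (5 up, 3 down), and fry called 7.

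The responses to BAPN of the 2 regions overlapped. Of the genes called, 391 were higher in both regions, 237 were lower in both, and 0 were called in opposite directions. Of the 2025 genes called in at least 1 region, 1867 (92.2%) had the same sign in both. Across all genes tested, which are not independent replicates, the log2 differences had r = 0.311 and rho = 0.397. With each region taken within a single batch r was 0.311 and rho 0.34, and with batch as a term 0.166 and 0.221. If same-numbered libraries share an animal, that alone could correlate the regions. Residual log2 CPM, split by number in 100 ways that mix the treatments, gave a median r of 0.0533 and at most 0.145. The real effects in log2 CPM had r = 0.378, and no such reference was computed with batch as a term. These splits do not cover a harvest time that followed treatment, raised below for the clock genes. It would act in both regions, and its share in the overlap was not tested. The 628 shared calls became 317 with batch as a term and 168 within single batches.

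**Figure D3:**
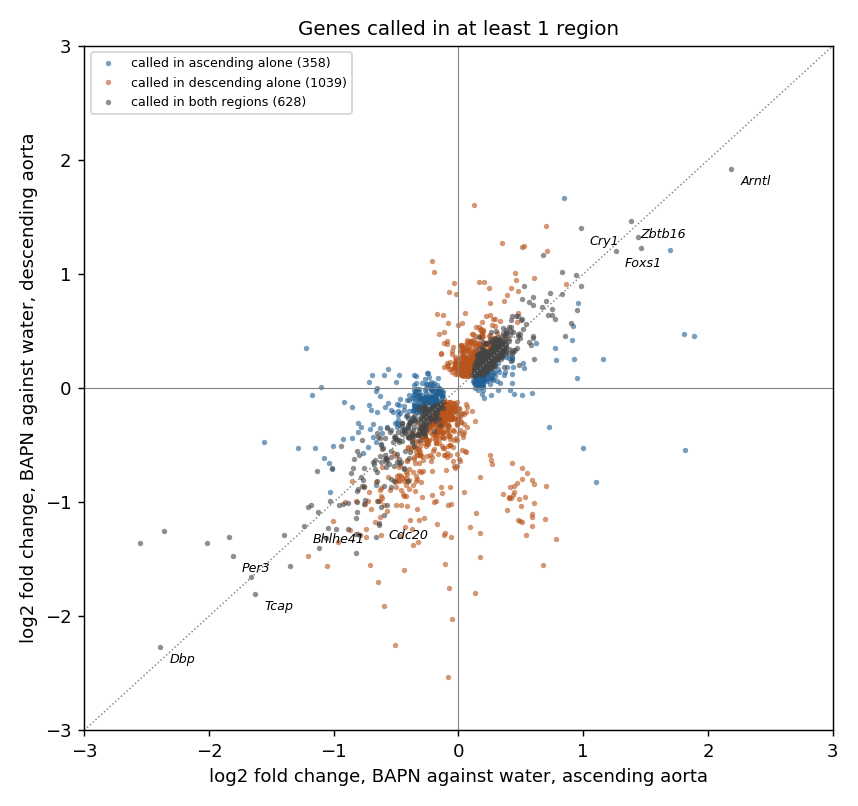
Log2 difference between BAPN and water in the ascending and the descending aorta for the genes called in at least 1 region (358 in the ascending alone, 1039 in the descending alone, 628 in both). The dotted line marks equal effects and 1 gene lies outside the axes.

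**Figure D4:**
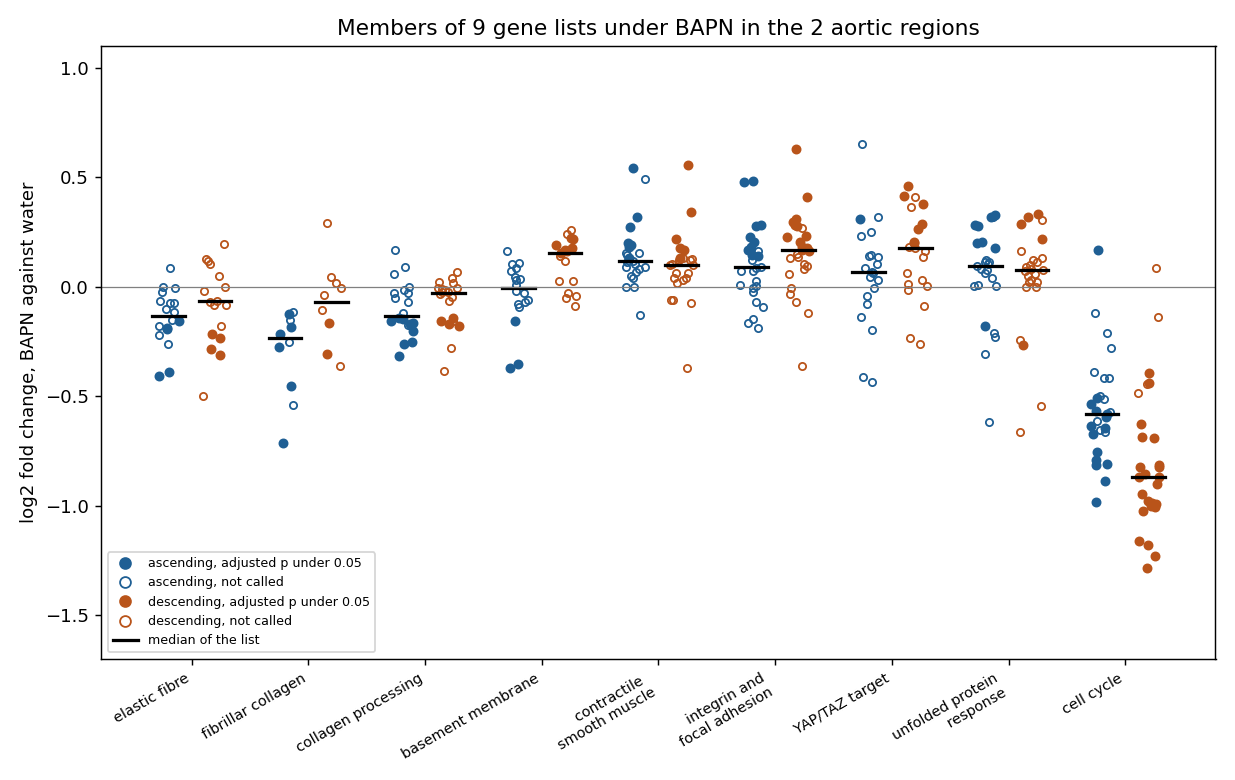
Log2 difference between BAPN and water for each member of 9 gene lists in each region. Filled points are called, bars are list medians, and Col2a1 in the descending aorta lies outside the axis.

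Whether the regions respond differently was tested as the difference of the BAPN effect between them, descending less ascending. The Lox effect was nearly the same in both (difference 0.00, SE 0.07). That of Eln was 0.18 higher in the descending aorta (SE 0.09, adjusted p = 0.757; -0.03, SE 0.11 with batch as a term), and that of Loxl1 0.15 higher (SE 0.07, adjusted p = 0.676); none of these passed. The genes with the smallest p, none of which passed (adjusted p = 0.216 each), were Fndc5 (-1.25, SE 0.24), Crim1 (0.31, SE 0.07), the histone chaperone Dnajc9 (-0.44, SE 0.10), Rasl10b (-0.90, SE 0.20) and the serine protease homologue Prss35 (0.73, SE 0.17). The BAPN effect on Fndc5 was -1.31 in the descending and -0.06 in the ascending aorta. Without descending water 4 Fndc5 was called (adjusted p = 0.049), and so were 16 genes in all, each lower; without descending BAPN 5, 1 gene was called. By edgeR 0 genes were called with all libraries taken as independent, and 1070 had an unadjusted p under 0.05. DESeq2 called 12, and edgeR without a filter on low counts 41. Taking the replicate number as a block, edgeR called Fndc5, Crim1 and Rasl10b among others, as given below. The labels do not say that a number marks an animal. With batch as a term 0 were called and 877 had an unadjusted p under 0.05, and no single batch holds all 4 groups.

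By lists, 12 of the 43 were called for a difference between regions, 6 in each direction, and 0 of them with an estimated correlation (adjusted p = 0.461 to 0.743) or by fry. Basement membrane genes lay higher in the descending response (adjusted p = 1.38e-07; 0.033 with batch as a term), as did the YAP/TAZ targets (0.0114; 0.011 with batch as a term). Endothelial marker genes lay higher too (median 0.143, adjusted p = 0.00235; 0.329, 8.1e-11 with batch as a term), a call lost without ascending water 4 (0.078). Cell cycle genes lay lower (4.4e-05; 7.5e-05 with batch as a term). The elastic fibre (0.0311) and fibrillar collagen lists (0.000388), higher in the descending response, were not called with batch as a term (0.91 and 0.15), and the fibrillar median (0.154) and mean (-0.105) differ in sign. In the lists alone, 4 basement membrane and 2 YAP/TAZ genes passed higher, and 0 elastic fibre, fibrillar collagen or cell cycle genes did. The YAP/TAZ call was lost without ascending BAPN 5 or descending water 1 (adjusted p = 0.052 each). That of the elastic fibre list was lost without ascending water 2, ascending BAPN 2, 4 or 5, descending water 1 or 2 or descending BAPN 1 (0.051 to 0.12).

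The largest differences between the regions under water were in genes of position along the body and of neighbouring tissues. Hoxb8, a homeobox gene of the posterior trunk (ENSMUSG00000056648, chromosome 11, 96281905 to 96285315), had a single count over the 5 ascending libraries and 23.3 (SD 2.07) CPM in the descending ones, a count ratio of 2273 (95% interval 407.5 to 89830). Hoxa7 was 256-fold higher in the descending aorta, at 39.6 (SD 4.87) against 0.14 (SD 0.09) CPM (adjusted p = 7.14e-20). Gata4, a cardiac transcription factor (ENSMUSG00000021944, chromosome 14, 63198922 to 63271692), was 363-fold lower, at 0.13 (SD 0.11) against 51.2 (SD 6.35), log2 -8.50 (SE 0.22). Hand2, which patterns the outflow tract, was 83.6-fold lower (log2 -6.39, SE 0.13). The Hox list had 15 higher and 0 lower of 20 (adjusted p = 5.52e-60, 3.87e-07 with an estimated correlation). The list of outflow tract and neural crest transcription factors had 13 lower and 5 higher of 24 (adjusted p = 5.09e-28, 1.23e-05 with an estimated correlation). Among the higher ones were Foxc2, Twist1, Prrx1 and Eya1, named after their values were seen. Also among the 8 genes highest in the descending aorta were Hoxb6 and Hoxb7 (count ratios 1346, interval 372.1 to 11120, and 789.2, interval 218.1 to 6523) and Hoxb5 (5.61, SE 0.22). The others were the sclerotome factor Pax1 (6.12, SE 0.26), the adipokine C1qtnf3 (4.62, SE 0.14) and the adrenergic receptor Adra2a (4.21, SE 0.15).

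Heart muscle transcripts were abundant in the ascending and scarce in the descending libraries. Tnnt2, cardiac troponin T (ENSMUSG00000026414, chromosome 1, 135836354 to 135852260), was at 197 (SD 46.1) CPM in ascending and 2.83 (SD 0.72) in descending aorta (log2 -6.10, SE 0.18, adjusted p = 7.58e-19). Myh6, the atrial myosin, was at 246 (SD 111) and 2.22 (SD 0.48), log2 -6.78 (SE 0.31). The genes lowest in the descending aorta were mostly of this kind: Csrp3, with 0 counts there, was at least 510-fold lower, and Mb had a count ratio of 1183 (interval 404.5 to 5740) and Sln of 509 (interval 140.6 to 4208). Myl3 was at -8.55 (SE 0.53) and Myl7 at -8.36 (SE 0.92; -12.6 within 1 batch). With them were Hand2os1, an RNA transcribed beside Hand2 (count ratio 1198, interval 409.7 to 5813), and the cartilage lectin Clec3a, at least 334.4-fold lower. The cardiomyocyte list had 0 higher and 18 lower of 19 (adjusted p = 3.43e-33, 0.00703 with an estimated correlation). The mesothelial list had 0 and 12 of 12 (2.97e-33, 0.00166), with the urothelial and mesothelial gene Upk3b at 152 against 2.19 CPM. The chondrocyte list had 0 and 13 of 14 (4.41e-15, 0.00276), with the cartilage regulator Sox9 at -3.03 (SE 0.13). The lymphatic endothelial list had 0 and 5 of 7 (2.85e-08, 0.0164), with its master regulator Prox1 at -4.36 (SE 0.24), and the Schwann cell list 0 and 7 of 12 (0.000391, 0.0164).

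Eln was higher in the descending than in the ascending aorta under water, at 47870 against 26580 CPM (log2 0.85, SE 0.07, adjusted p = 1.51e-10; 0.85 within the batch with the higher and 0.91 within that with the lower pseudogene level). Lox was higher by 0.65 (SE 0.05, adjusted p = 1.46e-10; 0.70 and 0.60 within the batches), Loxl3 by 0.38 (SE 0.05) and Loxl1 by 0.18 (SE 0.05). Loxl2 did not pass (0.01), nor did Loxl4 (0.25, SE 0.10, adjusted p = 0.061, or 0.046 without ascending BAPN 1). The family had 3 higher and 0 lower of 5 (adjusted p = 0.0102, 0.139 with an estimated correlation; adjusted over the list alone 4 and 0). Collagen processing had 14 higher and 0 lower of 20 (1.22e-06, 0.0785 with an estimated correlation; list alone 15 and 0), with the procollagen enhancer Pcolce2 at 0.75 (SE 0.04) and Sparc at 0.58 (SE 0.04). The fibrillar collagens, 4 higher (Col1a1, Col1a2, Col3a1 and Col5a1) and 3 lower of 10 (Col2a1, Col11a1 and Col11a2, named after their values were seen), were not called (0.75; median 0.148, mean -0.945). Elastic fibre genes went both ways, 4 higher and 8 lower of 18 (0.0321, 0.375 with an estimated correlation; list alone 5 and 8), with Efemp1 (-2.80, SE 0.13) and Fbln1 (-1.25, SE 0.06) lower. That list call was lost without descending water 1 or 2 (0.069 and 0.064). With batch as a term it was lost (0.056) while the median hardly moved, at -0.0611 against -0.0614. Within the batch with the lower level it was lost (0.25, median -0.0216), and within that with the higher level it was kept (0.007, median -0.112). The small matrix proteoglycans had 2 higher (Ogn and Podn, named after their values were seen) and 11 lower of 18 (7.31e-06, 0.0204 with an estimated correlation), with Lum at -1.11 (SE 0.07) and Dcn at -0.83 (SE 0.05).

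In all, 4243 genes were called between the regions under water, 1885 higher and 2358 lower in the descending aorta, and 1172 of them differed at least 2-fold (237 higher, 935 lower). The count was 4295 with batch as a term, 2537 within the batch with the higher (898 higher, 1639 lower; 2 ascending and 3 descending libraries) and 2601 within that with the lower pseudogene level (1019 higher, 1582 lower; 3 ascending and 2 descending). Of the 43 lists 18 were called, 6 higher and 12 lower, 8 of them with an estimated correlation, and fry called 26. Cell cycle genes were higher in the descending aorta (16 higher and 0 lower of 27, adjusted p = 0.000269, 0.376 with an estimated correlation; list alone 25 and 0), with the replication factor Mcm2 at 0.50 (SE 0.09). So were those of cholesterol synthesis (13 and 0 of 21, 0.000134, 0.375 with an estimated correlation; list alone 15 and 0), with the epoxidase Sqle at 0.80 (SE 0.10).

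**Figure D5:**
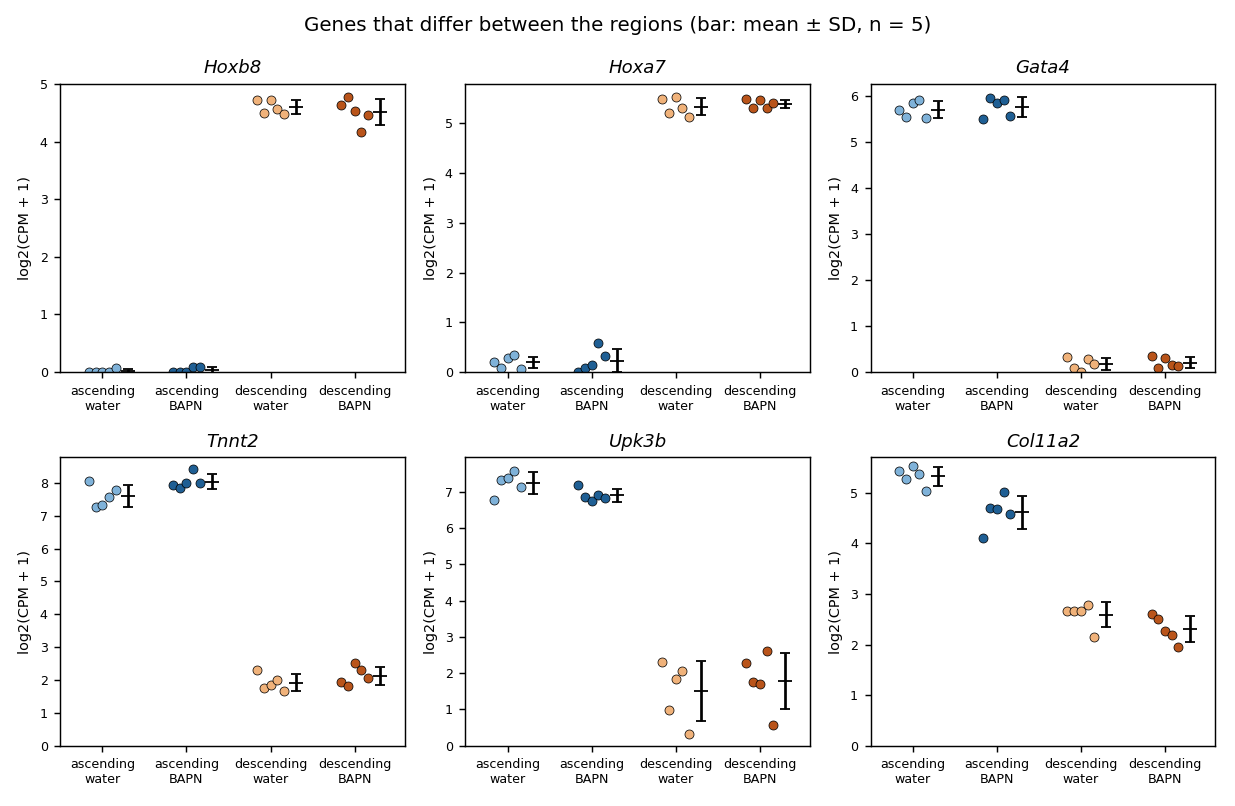
Levels, as log2 of CPM plus 1, of Hoxb8, Hoxa7, Gata4, Tnnt2, Upk3b and Col11a2 in each library of the 4 groups.

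Under BAPN the same kinds of genes parted the regions. Eln was higher in the descending aorta by 1.03 (SE 0.07) and Lox by 0.65 on the log2 scale (n = 5 libraries per group). The Hox list had 16 higher and 0 lower of 20 (adjusted p = 4.06e-60, 2.58e-07 with an estimated correlation), and collagen processing 14 and 0 of 20 (1.96e-08, 0.0386). The cardiomyocyte list had 0 and 18 of 19 (3.11e-40, 0.00317) and the mesothelial list 0 and 12 of 12 (1.26e-32, 0.00241). Cell cycle genes, with 5 higher and 0 lower of 27, were not called here (0.147), nor were elastic fibre genes (7 and 7 of 18, 0.277). In all, 4626 genes were called, 2206 higher and 2420 lower, 1292 of them at least 2-fold different (247 higher, 1045 lower). All ascending BAPN libraries lie in the batch with the higher pseudogene level and all descending BAPN libraries in the other, so no batch gives a value for this comparison, and with batch as a term 2755 genes were called (1131 higher, 1624 lower). Of the 43 lists 15 were called, 4 higher and 11 lower, 9 of them with an estimated correlation, and fry called 21.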

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

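The tests of explanations below were chosen after the patterns they address were seen. The tests of the difference between regions were planned.

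Clock genes shifted in both regions. Batch does not account for this, since 13 of 15, chosen because they had shifted, were called within 1 batch in the region where fewer were. Time of day at harvest may have differed between BAPN and water animals. Held-out targets of the same clock (Per1, Nr1d1 and Usp2) had a median log2 difference of -0.461 in the ascending and -0.354 in the descending aorta (camera p = 0.0135 and 0.0557, 0.0239 and 0.0712 with an estimated correlation). In each region 1 of the 3, Nr1d1, was called lower, but not within the batch (adjusted p = 0.359 and 0.132). Within the batch Per1 was called in the ascending aorta (0.0125) and not in the descending (0.232). Harvest time is not given and would follow the groups, so it cannot be told apart from an effect of BAPN on the clock. Higher glucocorticoid signalling was tested on induced genes that left out Fkbp5 and Zbtb16 (n = 13 genes, medians -0.00553 and 0.0642, 1 and 2 called higher, camera p = 0.525 and 0.0696); a median near 0 over genes that go both ways decides nothing, so it too cannot be told apart. An effect of BAPN itself stays open and untested.

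The split of the libraries by pseudogenes, 10 against 10, follows neither region nor treatment over all libraries. Of the 10 water libraries 5 lie on the higher side, from both regions. Among the BAPN libraries the split follows region exactly, with all 5 ascending ones on the higher and all 5 descending ones on the lower side. The split does not follow library size, as 7 libraries of the lower set have a total inside the range of the higher set. Reads of parent genes placed on pseudogenes may be its source, but the values cannot decide this. The 21 pseudogenes with a tested parent differed by a median log2 of 0.533, which is built in because these genes helped define the sets. The parents differed by 0.0195 (-0.0733 to 0.121), so their levels did not follow the sets. That would hold for misplaced reads and for other sources that act on the pseudogenes alone. Of all genes, 49 were called for the batch term, 38 of them higher. The mitochondrial genes mt-Co2 (-0.95, SE 0.24, adjusted p = 0.0095), mt-Atp6 (-0.96, SE 0.27, adjusted p = 0.023) and mt-Co3 (-0.91, SE 0.27, adjusted p = 0.030), chosen after their values were seen, were called lower under BAPN in the descending aorta, while mt-Atp6 and mt-Co2 differed by 1.22 and 1.04 on the log2 scale between the sets, against 0.15 for mt-Co1, and the lower set holds all 5 of these BAPN libraries. What differed between the sets (reads, trimming or run) was not tested, and no biological explanation was tested beyond region and treatment.

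Eln and the fibrillar collagens were lower under BAPN by more in the ascending than in the descending aorta, with a median difference of 0.16 on the log2 scale, 10 of 11 genes in that direction. With batch as a term the median was 0.0619, with 8 of 11, so batch may account for part of it, which is consistent with all ascending BAPN libraries lying in 1 set and all descending ones in the other. More heart muscle RNA in the ascending BAPN libraries would lower smooth muscle and matrix genes alike. The contractile list had a median of 0.118 there against -0.254 for the matrix genes. In the descending aorta its median was 0.0985, so it is no neutral measure of dilution. Its values argue against dilution as the whole cause only if BAPN acts on contractile genes alike in both regions, which was not tested. The contractile list also shares Pln with the cardiomyocyte list, so added heart RNA could itself raise part of it. A regional difference in the matrix response stays open, and for Eln the test of the difference did not pass (adjusted p = 0.757).

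For the difference of the BAPN effect between regions, the test of the difference picked out 12 lists by adjusted p: higher in the descending response were basement membrane (1.38e-07), fibrillar collagen (0.000388), endothelial (0.00235), YAP/TAZ targets (0.0114), elastic fibre (0.0311) and matricellular (0.0357), and lower were cell cycle (4.4e-05), oxidative phosphorylation (0.000222), cardiomyocyte (0.000888), lymphatic endothelial (0.00235), adipocyte (0.0312) and skeletal muscle genes (0.0456). None holds with an estimated correlation. Of them, basement membrane, YAP/TAZ, cell cycle and endothelial lists keep the call with batch as a term. Leaving out 1 library ended the calls of the endothelial list (ascending water 4, adjusted p = 0.078) and of YAP/TAZ targets (ascending BAPN 5 or descending water 1, 0.052 each). The same held for the elastic fibre list (ascending water 2, ascending BAPN 2, 4 or 5, descending water 1 or 2, descending BAPN 1; 0.051 to 0.12), the matricellular list (ascending water 3 or 5, ascending BAPN 1, 2 or 5, descending water 1 or 2, descending BAPN 1; 0.051 to 0.11), the adipocyte list (ascending water 2 or 3, ascending BAPN 1 or 4, descending water 2, descending BAPN 1 or 5; 0.064 to 0.45) and the skeletal muscle list (ascending water 2, 3 or 5, ascending BAPN 1, 4 or 5, descending water 2 or 4, descending BAPN 1, 2 or 5; 0.052 to 0.097).

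Single libraries stood apart from the other 4 of their group in 48 of 740 sets of 5 values checked; chance alone gives about 1 in 20. The value is the gap to the nearest library divided by the range of the group. In ascending water, library 1 was low in the elastic fibre score (0.72), Upk1b (0.737) and Efemp1 (0.716) and high in the fibrillar collagen score (0.754) and Comp (0.817). Library 2 was high in Zbtb16 (0.713) and Mfap5 (0.774), library 3 high in Hmgcs1 (0.779), and library 5 low in the score of outflow tract transcription factors (0.786) and high in Loxl4 (0.739). In ascending BAPN, library 1 was high in the fibroblast score (0.864) and Efemp1 (0.753) and low in Mfap5 (0.832) and Itgb1 (0.84), and library 2 low in the B cell score (0.942). Library 4 was low in the interferon score (0.796) and Ifit3 (0.854) and high in Tnnt2 (0.752), Cthrc1 (0.742) and Pax1 (0.833), and library 5 low in the cholesterol synthesis score (0.744) and Sqle (0.795). In descending water, library 1 was low in the lysyl oxidase score (0.841) and high in Cry1 (0.713) and Upk1b (0.949), library 2 high in the scores of fatty acid oxidation (0.882) and adipocytes (0.844) and in Loxl4 (0.73), library 3 low in Hspa5 (0.924) and high in Cthrc1 (0.783), library 4 high in Col9a3 (0.755) and library 5 low in Col11a2 (0.754). In descending BAPN, library 1 was high in Cdc20 (0.732) and Adamts4 (0.727), library 2 high in the scores of interferon response (0.93) and neutrophils (0.845) and in Ifit3 (0.814) and low in Actn1 (0.791), library 3 high in Actc1 (0.717), and library 5 high in total counts (0.77) and low in the matricellular score (0.827). A ratio of 1 marks a gene counted in a single library of its group: Hoxb8 in ascending water 5, Hoxb6 in ascending water 2 and ascending BAPN 2, Hoxb7 in ascending water 2 and ascending BAPN 1, and Sln in descending water 3.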

How the results depend on the processing

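The results with batch as a term or within a batch come from tests chosen after the data were seen; the other alternatives were planned. Under relative log expression factors, upper-quartile scaling, the stricter filter, limma-voom and, where it applies, the fit to the 2 compared groups alone, each count of genes and of lists, and the overlap, stayed within 1.5 times its value. The fit to 2 groups gives no value for the difference of effects. Upper-quartile scaling moved the balance of directions to 449 higher and 529 lower in the ascending and 706 and 874 in the descending response, and without a filter on low counts it was 434 and 517 in the ascending; the cause was not tested. Leaving out genes of other tissues gave 4172 calls between the regions under water and 4574 under BAPN.

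Without a filter on low counts, the difference of effects called 41 genes (11 higher, 30 lower) and 14 lists were called in the descending response. With DESeq2 the difference of effects called 12 genes and 19 lists, and the descending response 14 lists. With the replicate number as a block the difference of effects called 20 genes (4 higher, 16 lower), among them Fndc5 (adjusted p = 0.032), Crim1 (0.037) and Rasl10b (0.0033). The labels do not say that a number marks an animal. Same-numbered libraries had their own number as best match in 5 of 5 cases for the regions under BAPN (r = 0.064 to 0.11). Under water this held in 1 of 5 (-0.048 to 0.1), so these correlations alone leave the pairing unsettled. By the exact permutation test given below, scores of 5 of 43 gene lists deviated together by number within treatments, against 0 across them. The fits without a block take all libraries as independent. The cause of the changes in these counts was not tested. With batch as a term the ascending response had 542 calls, the regions under BAPN 2755 and the overlap 317. Within single batches the counts were 483 (ascending), 430 (descending), 2537 and 2601 (regions under water) and 168 (overlap); fewer libraries are compared there. With batch as a term the test of the lymphatic endothelial list in the difference of effects turned from down to up while its median stayed negative (-0.103), and the adipocyte median turned to 0.358. A size threshold of 1 on the log2 scale leaves 43, 113, 1172 and 1292 genes in the ascending, descending, water and BAPN comparisons by construction. With an estimated correlation 0 lists were called in the ascending response, 1 in the descending, 8 and 9 between the regions under water and BAPN, and 0 for the difference of effects, where fry also called 0; the estimated correlation exceeds the preset, and that widens the test.

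Leaving out 1 library at a time, the calls ranged from 719 to 1094 (ascending), 1240 to 1684 (descending), 3825 to 4448 (regions under water), 4267 to 4704 (under BAPN) and 494 to 634 (overlap). For the difference of effects they ranged from 0 to 16, the highest without descending water 4, and 1 was called without descending BAPN 5. Lists called ranged from 10 to 20 in the ascending response (20 without ascending water 1), 7 to 9 in the descending, 16 to 19 and 14 to 16 between the regions under water and BAPN, and 8 to 18 for the difference of effects. Over the named genes and the other settings, 2050 values kept direction and call, 85 lost the call, 20 gained it, and 10 changed sign without a call in either fit. With 1 library left out these were 4036, 89, 9 and 26. For lists called, 664 kept the call, 93 lost it and 2 reversed, and with 1 library left out 1244 kept and 56 lost it. Depth limits genes under the filter, while for the others the spread between 5 libraries limits the difference of effects, for which the smallest simulated changes were mostly missed.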

Other observations

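The test on library numbers below was chosen after the result was seen; the counts of other splits of the libraries were planned.

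Several gene lists lie outside the comparisons above. Under BAPN in the ascending aorta, oxidative phosphorylation genes lay higher as a list (adjusted p = 0.00247, 0.795 with an estimated correlation) with 0 of 23 members called, and melanocyte genes lay higher (0.0162, 0.454 with an estimated correlation) with 0 of 5 called. The melanocyte call was lost without ascending water 2 (0.083) or ascending BAPN 4 (0.099) and with batch as a term (0.14) or within the batch (0.16). TGF-beta ligands, receptors and targets, a pathway tied to aortic aneurysm, had 1 member higher (Skil, 0.35) and 1 lower (Bhlhe40, -0.58) of 20 in the ascending aorta (adjusted p = 0.982), and 2 of each in the descending (0.174; Skil and Tgfbr1 higher, Bhlhe40 and Smad3 lower). These genes were named after their values were seen, and Bhlhe40 is also in the set of clock genes chosen because they had shifted. The heat shock list had 1 member called in either region, Hsph1, at 0.72 (SE 0.16) and 0.64 (SE 0.16), named after its values were seen.

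Under water, the descending aorta had less transcript of genes of modulated smooth muscle (2 higher and 10 lower of 17, adjusted p = 0.000208, 0.0685 with an estimated correlation), where the higher members were the matrix genes Fn1 (0.82) and Tnc (1.97). Interferon response genes had 0 higher and 12 lower of 23 (0.0153, 0.803 with an estimated correlation), and fibroblast genes 6 higher and 10 lower of 20 (0.00813, 0.617 with an estimated correlation). Melanocyte genes had 0 higher and 5 lower of 5 (0.000114, 0.0793 with an estimated correlation). Adipocyte genes had 7 higher and 0 lower of 14 (0.0179, 0.803 with an estimated correlation), a call lost without descending water 2 (0.059, the median going from 0.767 to 0.436). Brown adipocyte genes, with 7 higher and 3 lower of 12, were not called (0.273).

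Other ways of splitting the same libraries were counted, 100 for each comparison. For BAPN against water the real split called 986 genes in the ascending aorta (highest other 11) and 1667 in the descending (highest other 546). For the regions it called 4243 under water (highest other 505) and 4626 under BAPN (highest other 92). In each of these comparisons only 1 of the 100, the real split, called as many genes. The other splits mix libraries of the compared groups, so a real difference widens the spread within their groups and leaves few calls. These counts therefore cannot decide whether chance is excluded. Under BAPN the real split of the regions is also the split by batch, so its count cannot part region from batch. For the difference of the BAPN effect between regions, 16 of the 100 splits gave as many genes at an unadjusted p under 0.05 as the real 1070. The highest other gave 2121. These splits shuffle BAPN and water libraries separately within each region, so a BAPN effect shared by the regions can enter their difference. They too cannot decide whether chance is excluded.

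Same-numbered ascending and descending libraries of 1 treatment deviated together, and the number may mark the animal. Over all 14400 pairings of numbers within treatments, an exact permutation test of the list scores passed for 5 of 43 lists after adjustment: heat shock and YAP/TAZ targets (adjusted p = 0.00896 each), immediate early genes (0.0289), and cholesterol synthesis and TGF-beta genes (0.0388 each). Pairing numbers across treatments, 0 of 43 lists passed. By the same exact permutation the clock genes gave p = 0.00194 within treatments and 0.926 across them. A shared day or order of harvest would give the same result as a shared animal and was not tested.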
